A study of Mus musculus with 20 samples.

How the data were processed

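Total RNA from the quadriceps muscle and the left ventricle of female mice aged 32 to 34 weeks was hybridised to Affymetrix MG_U74Av2 arrays, which carry short probes for mouse transcripts grouped into probe sets. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, cleaned on columns, and labelled as biotinylated cRNA starting from 8 µg. The 20 arrays fall into 4 groups of 5: quadriceps and left ventricle of C57BL/6 mice, which have normal dysferlin, and the same tissues of SJL/J mice. SJL/J is an inbred strain with an in-frame deletion in the dysferlin gene, and its limb muscles waste slowly with age. Strain and dysferlin genotype cannot be told apart in this design.

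The deposited values are 1 intensity per probe set and array on a linear scale, brought by the authors' array software to a common target. The trimmed means (2nd to 98th percentile) of the arrays lay between 199.4 and 199.9, and 0 values were negative. The software that summarised probes into probe sets, its background correction and its present or absent calls are not given in the sources used here. Chip lot and wash protocol were read per the file headers of the experiment reports: 2 chip lots and 2 wash protocols. The second protocol was used for SJL/J quadriceps array 1 alone. Fluidics runs were inferred from the hybridisation times in these headers, a longer gap starting a new run, which gave 5 runs.

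Of 12488 probe sets, 66 are controls, 10833 have 1 gene symbol, 396 have several and 1193 have none. Through gene identifiers, 10817 symbols were matched to a gene table of assembly GRCm38.p6 and 0 changed. No coordinates are given, because the arrays carry none and the build of their design is not given in the sources used here. Values under the 5th percentile (3.1) were set to it and log2 was taken. The deposited scaling was kept, since the trimmed means lay within 5% of each other. A probe set was tested if its mean in at least 1 group was above the median signal of 68.8. With the brightest probe set of each gene, 5392 genes were tested. For genes with other probe sets, agreement was checked: 29 of 198 followed entries had further tested probe sets, and in 7 of them 1 ran the opposite way (Myh4, Grn, H2-D1, Fhl1, H2-K1 and Etfb). Values for H2-D1, H2-K1 and others of the 20 entries read by probe sets that the array's naming marks as shared between related transcripts are uncertain. Sequence differences between the strains under the probes cannot be tested here.

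Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), within each tissue on its 10 arrays. The interaction used all 20 arrays, and the contrast of normal tissues used the 10 C57BL/6 arrays. Positive log2 values mean higher in SJL/J, in the interaction a higher strain difference in quadriceps, and in the tissue contrast higher in left ventricle. Errors of log2 values are standard errors with n = 5 per group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 25 lists with at least 4 tested members. Groups of 5 arrays were compared in single measures with a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3. The labels give 5 mice per group, and this number limits the precision. On simulated values with changes planted in 200 of 5392 genes, the fits recovered 74.6% of log2 changes of 1 in quadriceps, 65.7% in left ventricle, 38.8% in the interaction and 59.7% in the tissue contrast. At log2 changes of 0.5 these shares were 14.9%, 8.96%, 2.99% and 16.4%. The simulated noise was independent, with a single spread per gene averaged over the groups. It held no effect of run, RNA quality or transcripts of the other tissue. The shares therefore do not rank quadriceps, left ventricle and the tissue contrast, and recovery on the real arrays can differ.

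The groups, tests, 29 lists, threshold and the rule for named genes were fixed before the data were examined. That rule takes, per strain comparison, the 8 largest increases and 8 largest decreases among called genes whose 5 SJL/J values all lie beyond all 5 C57BL/6 values, and up to 4 members with the smallest p from each list described. It also takes the 6 largest interaction coefficients in each direction, the 5 largest tissue differences in each direction, and members of the complement lists. Lists described were those called in a comparison, in left ventricle also those called in quadriceps, and oxidative phosphorylation and sarcolemma in each strain comparison. These choices of lists were made later. The text gives examples from the 198 entries followed. Genes named outside the rule were chosen after their values were seen. They are Zap70, Jchain, Fabp4, Pfkl, Pgam1, Phka1, Hk2, Vwf, Hsp90b1, Hspb8, Hspa4, Cryab, Aqp1, Tie1, Flt1, Eng, Pkm, Tpi1, Pfkm, Myh6, Capn1, Capn2 and Aebp1. Alternatives covered scaling, floor, filter, probe sets, spread, threshold, test, blocks and each array left out. Alternatives on run 3, tissue shares and RNA quality were added after the data were seen. Probe sets with several or no symbols were left out of the gene counts. The targeted gene, dysferlin, is named by 0 probe sets, so it gives no check of the labels.

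For each array, a heart share and a skeletal share were computed as the median position between C57BL/6 tissue references, over 39 and 38 genes with over 16-fold difference between them. The references were median signals of the C57BL/6 quadriceps arrays of run 1 and left ventricle arrays of run 2. A strain index placed each array between C57BL/6 (0) and SJL/J (1) over 72 genes with over 2-fold strain difference in both tissues, 31 higher and 41 lower in SJL/J. Its SJL/J references were the left ventricle arrays of run 4 and the SJL/J quadriceps arrays of run 5. The arrays of run 3 and C57BL/6 quadriceps array 4 took no part in these definitions. The other arrays lie near 0 or 1 on the strain index partly by construction. All 3 measures were defined after the data were seen. As checks of RNA integrity, the ratio of the 5' to the 3' control probe sets was taken for Gapdh and actin. Among 190 pairs of arrays, 0 held identical values.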

Results

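Gene expression was measured in skeletal muscle and heart of dysferlin-deficient SJL/J mice and of C57BL/6 mice, which served as normal controls. Dysferlin is a membrane protein that takes part in resealing tears of the muscle fibre surface, and its loss causes a slowly progressing muscular dystrophy. Each of the 4 groups (C57BL/6 quadriceps, SJL/J quadriceps, C57BL/6 left ventricle and SJL/J left ventricle) held 5 arrays. The comparisons ask how skeletal muscle and heart of SJL/J mice differ from their normal counterparts, and which differences are particular to either tissue.

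Transcripts specific to the other tissue were found on several arrays, most on those of fluidics run 3. Among SJL/J quadriceps, arrays 1 and 5 carried heart transcripts at a heart share of 0.464 and 0.657 with skeletal shares of 0.4999 and 0.384, while arrays 2 to 4 had heart shares of at most 0.0952. Ryr2, the calcium release channel of heart muscle, read 1547 and 1673 on arrays 1 and 5 against 2.60 to 272 on the other 3. Tnnt2, cardiac troponin T, read 8979 and 9896 on them. In the left ventricle, SJL/J array 1 had a skeletal share of 0.146 and C57BL/6 array 5 one of 0.0632. These 4 arrays make up run 3. Outside it, SJL/J quadriceps array 3 (share 0.0952, Tnnt2 1182) and C57BL/6 quadriceps array 2 (heart share 0.0440, Tnnt2 546, Ryr2 139.5) carried some heart transcripts. The strain index of SJL/J quadriceps array 5 was 0.438, against 0.913 to 1.18 on the other SJL/J arrays and at most 0.159 on C57BL/6 arrays. Most of those arrays helped define the index, and array 5 did not. Of the others that did not, SJL/J quadriceps array 1 was at 1.02 and SJL/J left ventricle array 1 at 0.913. C57BL/6 left ventricle array 5 was at 0.159 and C57BL/6 quadriceps array 4 at 0.147. C57BL/6 quadriceps array 4 had the lowest median rank correlation with the other arrays of its group, 0.869.

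The measures of RNA integrity were lower in the SJL/J groups. The Gapdh 5' to 3' ratio was 0.831 ± 0.216 (SD, n = 5) in C57BL/6 and 0.503 ± 0.1496 (SD, n = 5) in SJL/J quadriceps (exact permutation p = 0.0476, adjusted p = 0.0476). In left ventricle it was 0.797 ± 0.0799 and 0.300 ± 0.134 (exact permutation p = 0.00794, adjusted p = 0.0159). The actin ratio was lower in SJL/J too, 0.715 ± 0.218 against 0.469 ± 0.0669 in quadriceps (exact permutation p = 0.0238, adjusted p = 0.0317). In left ventricle it was 0.593 ± 0.0415 against 0.271 ± 0.0908 (exact permutation p = 0.00794, adjusted p = 0.0159). Strain and fluidics run overlapped almost wholly. Run 5 alone held quadriceps of both strains (3 SJL/J and 1 C57BL/6 array), and run 3 alone held left ventricles of both (1 and 1). Within run 5 the Gapdh ratio ran the other way, 0.487 on the C57BL/6 array against 0.502 to 0.663 on the SJL/J arrays. The actin ratio kept its direction there, 0.640 against 0.463 to 0.516. The quadriceps Gapdh difference thus cannot be told apart from run or chip lot. In run 3 both left ventricle ratios were lower in SJL/J (Gapdh 0.470 against 0.865, actin 0.326 against 0.632). The C57BL/6 array of run 5 is array 4, the least correlated with its group, and the left ventricle pair of run 3 are the 2 arrays with skeletal shares of 0.146 and 0.0632. Every value with run as a block rests on these arrays. Chip lot 1 held only C57BL/6 quadriceps arrays 1, 2, 3 and 5, so with chip lot as a block array 4 alone stands for C57BL/6 quadriceps.

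**Figure D1:**
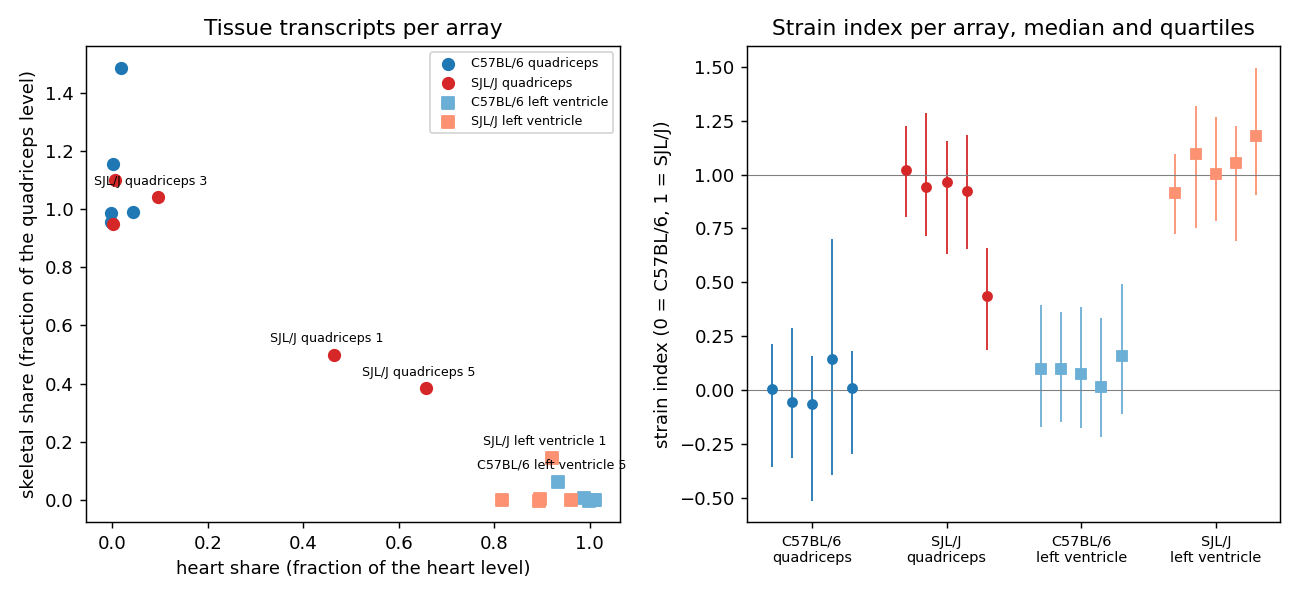
Left, heart share against skeletal share of each of the 20 arrays (both as a position between the C57BL/6 tissue references, no unit). Right, strain index per array (median and quartiles over 72 genes, 0 for C57BL/6 and 1 for SJL/J). SJL/J quadriceps arrays 1 and 5 lie between the tissues at heart shares of 0.464 and 0.657, and array 5 lies between the strains at 0.438.

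Ucp1, Cidea, Mmp12 and 5 further genes had the largest called increases in SJL/J quadriceps. Ucp1 is the uncoupling protein of brown fat mitochondria (4.29 ± 0.77, adjusted p = 0.00486), and its mean signal was 387 ± 493 (SD) against 11.7 ± 6.52. The latter lies under the filter signal of 68.8, and over the alternatives its log2 difference ran from 2.56 to 5.36, so the size of this increase is uncertain. Cidea, a lipid droplet protein of brown fat, also rose (3.73 ± 0.57, adjusted p = 0.00243), while the adipocyte list was not called. Mmp12, the macrophage elastase (3.86 ± 0.44, adjusted p = 0.00046), Ankrd1, an ankyrin repeat protein induced in loaded muscle (3.81 ± 0.59, adjusted p = 0.00258), and Rrad, a small GTPase of muscle (3.32 ± 0.25, adjusted p = 5.65e-05), rose. So did the metallothionein Mt2 (3.29 ± 0.48, adjusted p = 0.00202), the calcium-binding protein S100a4 (3.23 ± 0.46, adjusted p = 0.00173) and the immunoproteasome subunit Psmb9 (3.03 ± 0.50, adjusted p = 0.00334). The largest decreases were in Fgfbp1, which binds fibroblast growth factors (-3.12 ± 0.43, adjusted p = 0.00142), Inmt, an amine methyltransferase (-2.97 ± 0.48, adjusted p = 0.00306), and Snhg6, a small nucleolar RNA host gene (-2.82 ± 0.27, adjusted p = 0.00015). Pla2g12a (-2.49 ± 0.26), Pttg1, the securin of chromosome separation (-2.46 ± 0.43), Prps1l3 (-2.42 ± 0.24), Tfb2m, a mitochondrial transcription factor (-2.28 ± 0.35), and Zfp97 (-2.21 ± 0.42) fell as well, with limma adjusted p from 0.00015 to 0.00658. The lower group mean of Mmp12, Cidea, S100a4, Psmb9, Fgfbp1, Inmt and Zfp97 lay under 68.8 too, so their sizes and order are uncertain; over the alternatives Mmp12 ran down to 2.07, S100a4 to 2.67 and Psmb9 to 1.60. For these 16 genes all 5 SJL/J values lay beyond all 5 C57BL/6 values.

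Limma called 634 of the 5392 genes, 344 higher and 290 lower in SJL/J quadriceps, of which 178 and 94 changed at least 2-fold. In all, 1513 had an unadjusted p under 0.05. Among the called genes 490 had groups that did not overlap, as 639 of all genes did; chance gives 0.794%, or 42.8 genes. The split depended on scaling. Median centring moved the median of all genes by -0.149, from 0.09 to -0.06, and 220 of its 691 called genes were higher; with quantile normalization 269 of 591 were. Within run 5, 623 of the 634 genes (98.3%) kept their direction, the same arrays being part of the fit, and 945 genes were called with run as a block. Of the 634 calls 278 were kept there, 11 genes changed sign and 667 calls were new. Counts of genes called between SJL/J and C57BL/6 quadriceps were 411, 413 and 959 without C57BL/6 arrays 2, 3 and 4, and 411 and 419 without SJL/J arrays 2 and 3. With the Gapdh ratio as a covariate 279 were called, and without run 3 the count was 522. Fitting run as a block ended the calls of Cidea (2.27, adjusted p = 0.108), Tfb2m (-1.17, adjusted p = 0.0619) and Zfp97 (-2.02, adjusted p = 0.066). Chip lot as a block, which rests on C57BL/6 array 4 alone, also ended those of Ucp1 (3.27, adjusted p = 0.13) and Pttg1 (-2.27, adjusted p = 0.0735).

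In SJL/J quadriceps 4 immune lists were called higher with the preset correlation and 0 with an estimated one, and the B cell list was not called. Of 14 tested macrophage and monocyte markers, 9 rose, 0 fell and 5 did not pass the test. Macrophage markers had 12 higher and 0 lower when adjusted over the list alone, a median of 1.52 and camera adjusted p = 3.16e-07 (adjusted p = 0.0716 with an estimated correlation). Examples are Ctss, a cathepsin of antigen-presenting cells (2.80 ± 0.30, adjusted p = 0.000289), Mpeg1, a macrophage pore-forming protein (1.65 ± 0.16, adjusted p = 0.00015), and Csf1r, the receptor of macrophage growth factor (1.43 ± 0.26, adjusted p = 0.00486). Of 11 genes of MHC class I and antigen processing, 8 rose, 0 fell and 3 did not pass the test. MHC class I genes had 10 higher and 0 lower when adjusted over the list alone, a median of 1.09 and camera adjusted p = 6.11e-07 (adjusted p = 0.0716 with an estimated correlation). Among them were H2-D1 (1.70 ± 0.22), B2m, the light chain of class I molecules (1.28 ± 0.21), and the proteasome activator Psme1 (1.49 ± 0.19). Of 7 MHC class II genes, 4 rose, 0 fell and 3 did not pass the test. MHC class II genes had 4 higher and 0 lower when adjusted over the list alone, a median of 1.75 and camera adjusted p = 0.000163 (adjusted p = 0.0859 with an estimated correlation). The 4 were H2-Aa (2.69 ± 0.33), H2-Ab1 (2.43 ± 0.45), H2-Eb1 (1.95 ± 0.33) and the invariant chain Cd74 (1.75 ± 0.28). Of 16 interferon-stimulated genes, 8 rose, 0 fell and 8 did not pass the test. Interferon-stimulated genes had 11 higher and 0 lower when adjusted over the list alone, a median of 1.04 and camera adjusted p = 0.000163 (adjusted p = 0.19 with an estimated correlation). Examples are the transcription factors Irf9 (1.63 ± 0.37) and Irf1 (0.82 ± 0.15) and the guanylate-binding protein Gbp2 (1.24 ± 0.29). Macrophage, MHC class I and interferon-stimulated genes are also higher in normal left ventricle (medians 1.36, 1.43 and 1.23; adjusted p = 0.282, 0.141 and 0.476 with an estimated correlation). MHC class II had a median of 1.64 there (camera adjusted p = 0.0509). Heart transcripts on arrays 1 and 5 could thus have raised all 4 lists, which stayed called without run 3. Within run 5 the list medians were 2.11, 0.95, 2.05 and 1.46, in the order given. H2-Ab1 (2.05, adjusted p = 0.0926) and Irf1 (0.78, adjusted p = 0.055) lost their calls with run as a block. Irf9 (1.53, adjusted p = 0.0635) and Gbp2 (1.02, adjusted p = 0.0924) lost them without run 3.

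The matrix, regeneration, lysosomal and cardiac stress lists were called higher with the preset correlation alone, on arrays of which 1 and 5 also carried heart transcripts. Of 26 genes of extracellular matrix and fibrosis, 4 rose, 0 fell and 22 did not pass the test. Matrix genes had 4 higher and 0 lower when adjusted over the list alone, a median of 0.51 and camera adjusted p = 0.000249 (adjusted p = 0.189 with an estimated correlation). The rises were in Postn, periostin (2.29 ± 0.28, adjusted p = 0.000748), the proteoglycan Bgn (1.35 ± 0.25, adjusted p = 0.00512), the protease inhibitor Timp1 (1.62 ± 0.39, adjusted p = 0.0203) and the collagen cross-linking enzyme Lox (2.38 ± 0.63, adjusted p = 0.0299). Of 18 regeneration genes, 7 rose, 0 fell and 11 did not pass the test. Regeneration genes had 10 higher and 0 lower when adjusted over the list alone, a median of 0.90 and camera adjusted p = 0.000167 (adjusted p = 0.166 with an estimated correlation). Included were Myl4, a myosin light chain of developing muscle and of atria (2.53 ± 0.42, adjusted p = 0.00334), the myogenic factor Myog (1.18 ± 0.21, adjusted p = 0.00509) and Igf2 (1.08 ± 0.24, adjusted p = 0.0133). Of 20 lysosomal genes, 6 rose, 0 fell and 14 did not pass the test. Lysosomal genes had 6 higher and 0 lower when adjusted over the list alone, a median of 0.40 and camera adjusted p = 0.000819 (adjusted p = 0.189 with an estimated correlation). Among them were Grn (1.08 ± 0.21), Ctsb (0.81 ± 0.18) and Psap (0.67 ± 0.16). Of 9 cardiac stress and fetal genes, 3 rose, 0 fell and 6 did not pass the test. Cardiac stress genes had 4 higher and 0 lower when adjusted over the list alone, a median of 1.21 and camera adjusted p = 0.00207 (adjusted p = 0.0859 with an estimated correlation). Ankrd1 and Mt2 are given above, and Mt1 was the third (2.46 ± 0.41). Within run 5 the medians of the matrix, regeneration, lysosomal and cardiac stress lists were 0.89, 0.87, 0.63 and 0.33. The cardiac stress list was not called with run as a block (adjusted p = 0.363), nor with chip lot as a block (adjusted p = 0.328), where the regeneration list was not called either (median 0.72, adjusted p = 0.0996). The Lox call ended without C57BL/6 array 3 (2.34, adjusted p = 0.0637), SJL/J array 1 (2.30, adjusted p = 0.0636), SJL/J array 2 (2.38, adjusted p = 0.0588), SJL/J array 3 (2.34, adjusted p = 0.0626) or SJL/J array 4 (2.20, adjusted p = 0.0649). Timp1 was not called with run as a block (1.13, adjusted p = 0.193).

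Of 15 immediate early genes, which respond within minutes to stimuli, 6 rose, 1 fell and 8 did not pass the test. Immediate early genes had 9 higher and 1 lower when adjusted over the list alone, a median of 0.72 and camera adjusted p = 0.000249 (adjusted p = 0.189 with an estimated correlation). Of these, Btg2 (1.06 ± 0.16), Zfp36 (1.01 ± 0.16), Egr1 (1.40 ± 0.23) and Ier3 (1.35 ± 0.25) rose. Of 21 genes of the proteasome and muscle ubiquitin ligases, 0 rose, 3 fell and 18 did not pass the test. Proteasome genes had 0 higher and 3 lower when adjusted over the list alone, a median of -0.18 and camera adjusted p = 0.00955 (adjusted p = 0.525 with an estimated correlation). The 3 were the subunits Psma1 (-0.76 ± 0.18), Psmc2 (-0.53 ± 0.13) and Psma6 (-0.52 ± 0.14). Within run 5 the medians were 0.19 and -0.04, and with run as a block neither list was called (adjusted p = 0.202 and 0.653), nor was the immediate early list with chip lot as a block (adjusted p = 0.171). The proteasome call also ended with quantile normalization (adjusted p = 0.105), without run 3 (adjusted p = 0.591) and with the Gapdh covariate (adjusted p = 0.554). It ended as well with array weights (adjusted p = 0.121), with chip lot as a block (adjusted p = 0.171), with the tissue share as a covariate (adjusted p = 0.522), and without SJL/J array 1 (-0.12, adjusted p = 0.1) or SJL/J array 5 (-0.18, adjusted p = 0.052). The call of Psmc2 ended without C57BL/6 array 1 (-0.47, adjusted p = 0.0577), C57BL/6 array 2 (-0.48, adjusted p = 0.067) or SJL/J array 3 (-0.50, adjusted p = 0.0658). The call of Psma6 ended without C57BL/6 array 1 (-0.52, adjusted p = 0.0612), C57BL/6 array 2 (-0.53, adjusted p = 0.0675), C57BL/6 array 3 (-0.48, adjusted p = 0.0869), C57BL/6 array 5 (-0.53, adjusted p = 0.0549), SJL/J array 1 (-0.47, adjusted p = 0.0699), SJL/J array 3 (-0.51, adjusted p = 0.0797), SJL/J array 4 (-0.53, adjusted p = 0.0657) or SJL/J array 5 (-0.50, adjusted p = 0.0669). Psma1, with run as a block, was at -0.12, adjusted p = 0.712.

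Complement genes were listed because complement attack on fibres is studied in dysferlin deficiency. Cd55, which shields cells from complement, fell in SJL/J quadriceps (-2.19 ± 0.44, adjusted p = 0.00794), from a mean signal of 152 ± 92.9 (SD) to 29.3 ± 8.58, with no overlap between the groups. The latter mean is under the filter signal of 68.8. C1qa (1.72 ± 0.34, adjusted p = 0.00741) and C1qc (1.01 ± 0.25, adjusted p = 0.0234), chains of the first component, rose, and so did Cd59a, an inhibitor of the membrane attack complex (0.91 ± 0.26, adjusted p = 0.0378). C2 was at 1.21 ± 0.43, adjusted p = 0.0826, and Cd59b at -0.82 ± 0.27, adjusted p = 0.0665. Of 7 tested components, 2 rose, 0 fell and 5 did not pass the test. Complement components had 4 higher and 0 lower when adjusted over the list alone, a median of 0.69 and camera adjusted p = 0.119 (adjusted p = 0.251 with an estimated correlation). Of 7 tested regulators, 1 rose, 1 fell and 5 did not pass the test. Complement regulators had 1 higher and 2 lower when adjusted over the list alone, a median of 0.48 and camera adjusted p = 0.838 (adjusted p = 0.938 with an estimated correlation). Their mean was -0.16, opposite in sign to the median, and the test's direction was down. Within run 5 Cd55 was at -0.65, and its call ended with run as a block (adjusted p = 0.451) and with the Gapdh covariate (-1.59, adjusted p = 0.116). The call of C1qc ended without C57BL/6 array 3 (0.92, adjusted p = 0.0594), SJL/J array 2 (0.94, adjusted p = 0.0573), SJL/J array 3 (0.99, adjusted p = 0.0522) or SJL/J array 4 (0.94, adjusted p = 0.0542). The call of Cd59a ended without C57BL/6 array 2 (0.91, adjusted p = 0.0756), C57BL/6 array 3 (0.88, adjusted p = 0.0838), SJL/J array 1 (0.84, adjusted p = 0.0828), SJL/J array 2 (0.94, adjusted p = 0.065), SJL/J array 3 (0.95, adjusted p = 0.0648), SJL/J array 4 (0.98, adjusted p = 0.0514) or SJL/J array 5 (0.85, adjusted p = 0.0747). Cd59b passed the threshold without C57BL/6 array 4 (-0.90, adjusted p = 0.0452) or SJL/J array 5 (-1.03, adjusted p = 0.0183).

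Other groups gave no list call in quadriceps. Of 19 sarcolemma and membrane repair genes, 6 rose, 0 fell and 13 did not pass the test. Sarcolemma genes had 6 higher and 2 lower when adjusted over the list alone, a median of 0.23 and camera adjusted p = 0.427 (adjusted p = 0.669 with an estimated correlation). Rises were in the annexin-associated S100a10 (1.12 ± 0.22), Anxa2 (1.27 ± 0.26), Anxa4 (0.83 ± 0.17) and Anxa5 (0.80 ± 0.16). Of 42 oxidative phosphorylation genes, 2 rose, 0 fell and 40 did not pass the test. Oxidative phosphorylation genes had 2 higher and 0 lower when adjusted over the list alone, a median of 0.08 and camera adjusted p = 0.664 (adjusted p = 0.886 with an estimated correlation). Sdhd (0.78 ± 0.17) and Cox6a1 (1.05 ± 0.24) were the rises. Of 20 glycolysis and glycogen genes, 2 rose, 2 fell and 16 did not pass the test. Glycolysis genes had 3 higher and 4 lower when adjusted over the list alone, a median of -0.17 and camera adjusted p = 0.239 (adjusted p = 0.669 with an estimated correlation). Of these, Pfkl (1.40 ± 0.24) and Pgam1 (1.09 ± 0.24) rose while Phka1 (-1.18 ± 0.30) and Hk2 (-0.55 ± 0.14) fell. Of 21 fatty acid genes, 0 rose, 0 fell and 21 did not pass the test. Fatty acid genes had 0 higher and 0 lower when adjusted over the list alone, a median of 0.42 and camera adjusted p = 0.111 (adjusted p = 0.669 with an estimated correlation). Of 12 fast-twitch contractile genes, 0 rose, 0 fell and 12 did not pass the test. Fast-twitch genes had 0 higher and 0 lower when adjusted over the list alone, a median of -0.08 and camera adjusted p = 0.417 (adjusted p = 0.846 with an estimated correlation). Of 10 slow-twitch genes, 0 rose, 0 fell and 10 did not pass the test. Slow-twitch genes had 0 higher and 0 lower when adjusted over the list alone, a median of 1.01 and camera adjusted p = 0.194 (adjusted p = 0.678 with an estimated correlation). Within run 5 the slow-twitch median was -1.04. Cox6a1, with run as a block, was at 0.52, adjusted p = 0.396 and Anxa5 at 0.88, adjusted p = 0.0541, and Sdhd was at 0.63, adjusted p = 0.053 with median centring.

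Markers of further cell types were tested in quadriceps as lists. Of 12 endothelial markers, 0 rose, 1 fell and 11 did not pass the test. Endothelial markers had 0 higher and 1 lower when adjusted over the list alone, a median of 0.20 and camera adjusted p = 0.885 (adjusted p = 0.956 with an estimated correlation). The decrease was in Vwf (-0.75 ± 0.19). Of 12 fibroblast markers, 1 rose, 0 fell and 11 did not pass the test. Fibroblast markers had 1 higher and 0 lower when adjusted over the list alone, a median of 0.23 and camera adjusted p = 0.296 (adjusted p = 0.678 with an estimated correlation). The increase was in S100a4. Of 8 adipocyte markers, 1 rose, 0 fell and 7 did not pass the test. Adipocyte markers had 4 higher and 0 lower when adjusted over the list alone, a median of 0.64 and camera adjusted p = 0.194 (adjusted p = 0.669 with an estimated correlation). The increase was in Fabp4 (0.62 ± 0.17). Of 17 heat shock and chaperone genes, 1 rose, 0 fell and 16 did not pass the test. Chaperone genes had 1 higher and 0 lower when adjusted over the list alone, a median of 0.42 and camera adjusted p = 0.194 (adjusted p = 0.266 with an estimated correlation). The increase was in Hsp90b1 (1.34 ± 0.23). Of 5 B and plasma cell markers, 1 rose, 0 fell and 4 did not pass the test. B cell markers had 1 higher and 0 lower when adjusted over the list alone, a median of -0.29 and camera adjusted p = 0.805 (adjusted p = 0.846 with an estimated correlation). Jchain rose (1.70 ± 0.48), and the list mean of 0.07 was opposite in sign to the median. Of 4 red blood cell markers, 0 rose, 0 fell and 4 did not pass the test. Red blood cell markers had 0 higher and 0 lower when adjusted over the list alone, a median of -0.31 and camera adjusted p = 0.54 (adjusted p = 0.839 with an estimated correlation). Of 6 Schwann cell and nerve markers, 0 rose, 0 fell and 6 did not pass the test. Nerve markers had 0 higher and 0 lower when adjusted over the list alone, a median of 0.36 and camera adjusted p = 0.423 (adjusted p = 0.669 with an estimated correlation). Lists of under 4 tested genes got no set test: of 2 T and NK cell markers 1 rose (Zap70, 1.32 ± 0.39), of 3 atrial markers 1 rose (Myl4), and of 3 neutrophil and 2 mast cell markers 0 were called by limma, 0 also when adjusted over the list alone. In all 10 of the 25 lists were called with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0716.

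**Figure D2:**
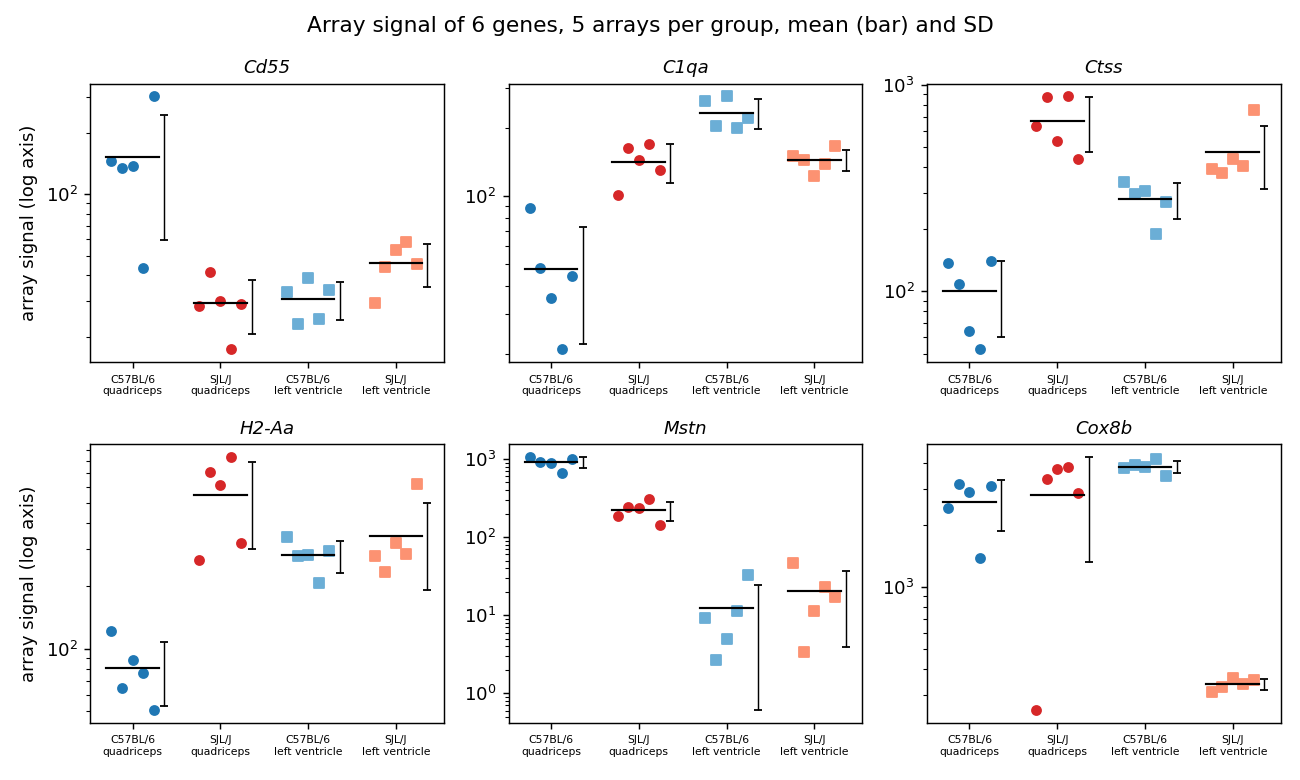
Signal (deposited units, log axis) of 6 genes on each array by group, with bars at the group means and error bars of 1 SD. Cd55 fell in SJL/J quadriceps, C1qa, Ctss and H2-Aa rose there, Mstn is shown for the interaction, and Cox8b fell in SJL/J left ventricle and read 252.5 on SJL/J quadriceps array 1.

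The largest called decreases in SJL/J left ventricle included 4 mitochondrial subunits, while the oxidative phosphorylation list was not called (median -0.09, camera adjusted p = 0.217). Cox8b, a cytochrome c oxidase subunit (-3.51 ± 0.09, adjusted p = 1.57e-11), Uqcr11, of complex III (-3.27 ± 0.09, adjusted p = 3.09e-11), and the ATP synthase subunits Atp5e (-3.53 ± 0.19, adjusted p = 4.25e-08) and Atp5k (-3.06 ± 0.41, adjusted p = 0.000143) fell. Fkbp8 (-3.63 ± 0.26, adjusted p = 6.67e-07), the heparan sulfate proteoglycan Sdc4 (-3.09 ± 0.34, adjusted p = 3.36e-05) and the cytokine Il15 (-2.96 ± 0.28, adjusted p = 1.08e-05) were among the other large decreases, as was a probe set that carries the symbol of a microRNA. Increases were led by Socs1, an inhibitor of cytokine signalling (2.26 ± 0.24, adjusted p = 2.61e-05), the importin Kpna2 (2.08 ± 0.12, adjusted p = 1.17e-07), the guanylate-binding protein Gbp7 (2.07 ± 0.29, adjusted p = 0.000238) and Gatm, an enzyme of creatine synthesis (2.04 ± 0.21, adjusted p = 1.90e-05). Zfp30 (1.89 ± 0.12), Wdr92 (1.88 ± 0.14), the urinary protein Mup5 (1.88 ± 0.45) and Ocel1 (1.83 ± 0.12) followed. For each of these genes all 5 SJL/J values lay beyond all 5 C57BL/6 values. On SJL/J quadriceps array 1, Cox8b read 252.5 against 2850 to 3821 on arrays 2 to 5, below the 307.7 to 361.9 of SJL/J left ventricle. Uqcr11 read 166.2 there, below the 350.9 to 434.5 of SJL/J left ventricle, and Atp5e 111.3, inside its 103.8 to 234.7.

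Limma called 1822 of 5392 genes in left ventricle, 961 higher and 861 lower in SJL/J, of which 105 and 239 changed at least 2-fold. In all, 2383 had an unadjusted p under 0.05. Groups did not overlap for 1153 of the called genes and 1190 of all genes, where chance gives 0.794% (42.8 genes). The Gapdh 5' to 3' ratio differed most here, 0.797 against 0.300, and with it as a covariate 256 genes were called. They held 215 of the 1822, and 95 of the 1822 changed sign. Within run 3, 1716 of the 1822 genes (94.2%) kept their direction in 1 array against 1, both also in the fit. Fewer genes, 48, were called with run as a block, 44 of the 1822 among them, and 106 changed sign. Among the largest changes, the calls of Socs1 (1.82, adjusted p = 0.169), Gbp7 (0.99, adjusted p = 0.588), Gatm (1.54, adjusted p = 0.2), Mup5 (3.06, adjusted p = 0.137), Sdc4 (-1.35, adjusted p = 0.154), Atp5k (-1.61, adjusted p = 0.49) and Il15 (-3.001, adjusted p = 0.0616) ended with run as a block. With the Gapdh covariate those of Gbp7 (1.07, adjusted p = 0.162), Mup5 (2.37, adjusted p = 0.119) and Atp5k (-1.14, adjusted p = 0.0581) ended.

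No list was called in left ventricle: camera called 0 of 25 lists (smallest adjusted p = 0.217, or 0.828 with an estimated correlation) and 5 had an unadjusted p under 0.05. Of 42 oxidative phosphorylation genes, 8 rose, 12 fell and 22 did not pass the test. Oxidative phosphorylation genes had 8 higher and 12 lower when adjusted over the list alone, a median of -0.09 and camera adjusted p = 0.217. Falls were in Cox7a1 (-2.10 ± 0.11) and Cox5b (-1.11 ± 0.08) besides Cox8b and Atp5e. Of 16 interferon-stimulated genes, 8 rose, 2 fell and 6 did not pass the test. Interferon-stimulated genes had 9 higher and 2 lower when adjusted over the list alone, a median of 0.69 and camera adjusted p = 0.217. Of these, Irf9 (0.97 ± 0.12), Ifi204 (1.18 ± 0.19) and Gbp3 (0.97 ± 0.18) rose and Rsad2 (-1.26 ± 0.25) fell. Of 11 MHC class I genes, 4 rose, 0 fell and 7 did not pass the test. MHC class I genes had 4 higher and 0 lower when adjusted over the list alone, a median of 0.37 and camera adjusted p = 0.217. Included were Psmb9 (0.87 ± 0.18), H2-D1 (0.60 ± 0.13) and B2m (0.56 ± 0.16). Of 20 glycolysis genes, 3 rose, 8 fell and 9 did not pass the test. Glycolysis genes had 3 higher and 9 lower when adjusted over the list alone, a median of -0.25 and camera adjusted p = 0.23. Of 12 endothelial markers, 1 rose, 6 fell and 5 did not pass the test. Endothelial markers had 1 higher and 6 lower when adjusted over the list alone, a median of -0.43 and camera adjusted p = 0.217. Within run 3 the medians of these 5 lists were -0.02, 0.32, 0.17, 0.08 and -0.07. With the Gapdh covariate the calls of Ifi204, Gbp3, Psmb9 and H2-D1 ended (adjusted p = 0.19, 0.365, 0.456 and 0.248), and B2m was at -0.05, adjusted p = 0.909. Over all alternatives the lowest log2 differences of Ifi204, Gbp3, Psmb9 and H2-D1 were 0.36, 0.27, 0.40 and 0.45. The Gapdh ratio was 0.697 to 0.866 in C57BL/6 and 0.101 to 0.470 in SJL/J left ventricle, so this covariate overlaps with strain there. With run as a block, which rests on 1 array against 1, B2m, H2-D1, Psmb9, Irf9 and Rsad2 lost their calls but kept their direction. Their log2 differences within run 3 were 0.37, 0.45, 0.85, 0.82 and -2.04.

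Lists called in quadriceps were not called in left ventricle. Of 14 macrophage markers, 5 rose, 2 fell and 7 did not pass the test. Macrophage markers had 5 higher and 2 lower when adjusted over the list alone, a median of 0.32 and camera adjusted p = 0.397. Cd53 (1.72 ± 0.30), Ctss (0.73 ± 0.20) and Csf1r (0.61 ± 0.17) were among the rises. Of 7 MHC class II genes, 1 rose, 1 fell and 5 did not pass the test. MHC class II genes had 1 higher and 0 lower when adjusted over the list alone, a median of 0.23 and camera adjusted p = 0.601. H2-Eb1 (0.75 ± 0.20) rose and H2-Ab1 (-0.70 ± 0.25) fell. The H2-Ab1 call ended without C57BL/6 array 1 (-0.60, adjusted p = 0.109), C57BL/6 array 2 (-0.72, adjusted p = 0.0731), C57BL/6 array 3 (-0.68, adjusted p = 0.089), C57BL/6 array 5 (-0.69, adjusted p = 0.0856), SJL/J array 2 (-0.62, adjusted p = 0.103), SJL/J array 3 (-0.66, adjusted p = 0.095) or SJL/J array 4 (-0.56, adjusted p = 0.115). Of 26 matrix genes, 6 rose, 2 fell and 18 did not pass the test. Matrix genes had 6 higher and 2 lower when adjusted over the list alone, a median of 0.10 and camera adjusted p = 0.601. Postn (0.99 ± 0.16) rose and the collagen chaperone Serpinh1 (-2.39 ± 0.20) fell. Of 18 regeneration genes, 1 rose, 3 fell and 14 did not pass the test. Regeneration genes had 1 higher and 2 lower when adjusted over the list alone, a median of 0.23 and camera adjusted p = 0.805. The test's direction was down for the latter, against its median and mean (0.08). Csrp3 (-1.29 ± 0.09) and Ankrd1 (-1.19 ± 0.12) fell. Of 19 sarcolemma genes, 3 rose, 6 fell and 10 did not pass the test. Sarcolemma genes had 3 higher and 6 lower when adjusted over the list alone, a median of -0.22 and camera adjusted p = 0.244. Sspn, sarcospan (-2.22 ± 0.15), Anxa6 (-1.01 ± 0.14), Capn1 (-1.13 ± 0.31) and Capn2 (-0.96 ± 0.19) were among the falls and Anxa1 (1.09 ± 0.17) among the rises. Ctss, with run as a block, was at 0.53, adjusted p = 0.734, Cd53 at 1.29, adjusted p = 0.532, Postn at 0.51, adjusted p = 0.589, Ankrd1 at -1.24, adjusted p = 0.0855 and Anxa1 at 0.79, adjusted p = 0.393.

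The C1q chains ran opposite to quadriceps in left ventricle, where C1qa (-0.69 ± 0.13, adjusted p = 0.00195) and C1qc (-0.77 ± 0.12, adjusted p = 0.000428) fell. Cd59b fell as well (-1.21 ± 0.12, adjusted p = 1.22e-05). Vtn, vitronectin, fell too (-1.68 ± 0.33, adjusted p = 0.00202), while Serping1, the inhibitor of the first component, rose (0.80 ± 0.17, adjusted p = 0.00398). Cd55 was at 0.58 ± 0.26, adjusted p = 0.11, at 0.73 without SJL/J array 1 (adjusted p = 0.0337), and at -0.21 within run 3. Of 7 components, 0 rose, 2 fell and 5 did not pass the test. Complement components had 0 higher and 2 lower when adjusted over the list alone, a median of -0.32 and camera adjusted p = 0.397. Of 7 regulators, 1 rose, 2 fell and 4 did not pass the test. Complement regulators had 1 higher and 2 lower when adjusted over the list alone, a median of -0.06 and camera adjusted p = 0.601. With the Gapdh covariate C1qa was at -0.85, adjusted p = 0.0532, C1qc at -0.75, adjusted p = 0.061, Vtn at -0.58, adjusted p = 0.518 and Serping1 at 0.14, adjusted p = 0.77. Cd59b, with run as a block, was at -1.07, adjusted p = 0.122 and C1qa at -0.56, adjusted p = 0.554. The other lists had camera adjusted p of 0.398 (fatty acid, 2 rose and 6 fell), 0.397 (lysosomal, 4 and 6), 0.397 (proteasome, 5 and 7) and 0.371 (cardiac stress, 1 and 2).

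Genes that differed between the strains in both tissues numbered 240, and 171 of them changed in the same direction. Pttg1 fell in both (-2.46 in quadriceps and -2.60 in left ventricle), as did Snhg6 (-2.82 and -2.24), Tfb2m (-2.28 and -1.83), Il15 (-1.77 and -2.96), Zfp97 (-2.21 and -1.67) and Aebp1 (-2.16 and -1.51). Gatm (2.46 and 2.04) and Wdr92 (1.69 and 1.88) rose in both. These 8 had the largest smaller change among 87 genes with no overlap in either tissue. By direction, 87 genes rose in both where independent lists would share 61.3 (hypergeometric adjusted p = 0.000422), and 84 fell in both where they would share 46.3 (adjusted p = 2.69e-08). The other 69 went opposite ways, 37 of them higher in quadriceps, against 54.9 for independent lists. The hypergeometric test treats genes as independent draws, which they are not, so its p-values do not measure a shared strain effect. Strain also overlaps with fluidics run and RNA integrity in both tissues, and the overlap of the lists cannot be told apart from these. Across genes, which are not independent replicates, the strain differences of the tissues correlated at r = 0.198. Of genes called in both tissues in the same direction, 53 of 171 were higher with median centring and 67 of 157 with quantile normalization. The count was 6 with run as a block and 24 with the Gapdh covariate.

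The strain difference itself differed between tissues for 875 genes in the interaction fit, 505 in favour of quadriceps and 370 of left ventricle, with 1690 at an unadjusted p under 0.05. Ankrd1 (5.00 ± 0.66, adjusted p = 9.31e-05), Rrad (4.53 ± 0.32, adjusted p = 1.74e-08), Ucp1 (4.40 ± 1.10, adjusted p = 0.00963), Cidea (4.01 ± 0.64, adjusted p = 0.000407), Mt2 (3.80 ± 0.58, adjusted p = 0.000266) and the cyclin Ccnd2 (3.74 ± 0.99, adjusted p = 0.0137) had the largest positive values. Negative values were largest for Mup5 (-2.98 ± 0.69, adjusted p = 0.00615), Pla2g7 (-2.88 ± 0.24, adjusted p = 2.60e-07), Mstn, the growth inhibitor myostatin (-2.81 ± 0.80, adjusted p = 0.021), Fgfbp1 (-2.81 ± 0.77, adjusted p = 0.0174), Cd55 (-2.77 ± 0.53, adjusted p = 0.00164) and Socs1 (-2.60 ± 0.36, adjusted p = 0.000163). Complement C1qa (2.40 ± 0.37), C1qc (1.78 ± 0.29) and Cd59a (1.14 ± 0.32) differed as well, Cd59a not without run 3 (0.90, adjusted p = 0.093). Median centring moved the median of all genes by -0.153 and left 311 of 849 called genes higher; with quantile normalization 421 of 827 were. Without C57BL/6 quadriceps array 4 the count of genes whose strain difference differs between quadriceps and left ventricle was 1339, with run as a block 284, and with run as a random block 208. Several did not pass with run as a block: Ucp1 (1.90, adjusted p = 0.618), Cidea (2.29, adjusted p = 0.287), Ccnd2 (1.91, adjusted p = 0.519), Mup5 (-4.44, adjusted p = 0.0604), Mstn (-1.86, adjusted p = 0.407), Fgfbp1 (-1.82, adjusted p = 0.55), Cd55 (-0.44, adjusted p = 0.811), C1qc (1.79, adjusted p = 0.0785) and Socs1 (-2.43, adjusted p = 0.0519).

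As groups, 10 of 25 lists had a higher strain difference in quadriceps than in left ventricle with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.152), while 12 had an unadjusted p under 0.05. They were macrophage markers (7 up and 0 down of 14, median 1.18, camera adjusted p = 0.000218), MHC class I (6 up and 0 down of 11, median 0.82, camera adjusted p = 0.00182), MHC class II (3 up and 0 down of 7, median 1.196, camera adjusted p = 0.00862), lysosomal genes (7 up and 0 down of 20, median 0.55, camera adjusted p = 0.00114) and cardiac stress genes (3 up and 0 down of 9, median 1.02, camera adjusted p = 0.00532). Matrix (4 up and 0 down of 26, median 0.46, camera adjusted p = 0.0112), regeneration (6 up and 0 down of 18, median 0.80, camera adjusted p = 0.0211), immediate early (6 up and 0 down of 15, median 0.37, camera adjusted p = 0.00862) and fatty acid genes (4 up and 0 down of 21, median 0.46, camera adjusted p = 0.0116) followed. The sarcolemma list (5 up and 1 down of 19, median 0.50, camera adjusted p = 0.0366) was not called without C57BL/6 quadriceps array 4 (0.37, adjusted p = 0.0501), SJL/J quadriceps array 2 (0.53, adjusted p = 0.0601), SJL/J quadriceps array 3 (0.50, adjusted p = 0.0661), SJL/J quadriceps array 4 (0.49, adjusted p = 0.0531) or SJL/J left ventricle array 3 (0.50, adjusted p = 0.0507). Complement components (2 up and 0 down of 7, median 0.93, camera adjusted p = 0.0607) were called without C57BL/6 quadriceps array 1 (0.93, adjusted p = 0.0304), C57BL/6 quadriceps array 5 (0.89, adjusted p = 0.0412), C57BL/6 left ventricle array 4 (0.93, adjusted p = 0.0381), SJL/J left ventricle array 4 (1.02, adjusted p = 0.0404) or SJL/J left ventricle array 5 (1.16, adjusted p = 0.0327). With run as a block the class I, regeneration, sarcolemma, cardiac stress, fatty acid and immediate early lists were not called (adjusted p = 0.0535, 0.0759, 0.104, 0.236, 0.0535 and 0.404), and without run 3 the fatty acid list was not (adjusted p = 0.126). With chip lot as a block 7 lists were called, and the class I, regeneration, sarcolemma, cardiac stress and immediate early lists were not (adjusted p = 0.0612, 0.283, 0.153, 0.153 and 0.262).

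**Figure D3:**
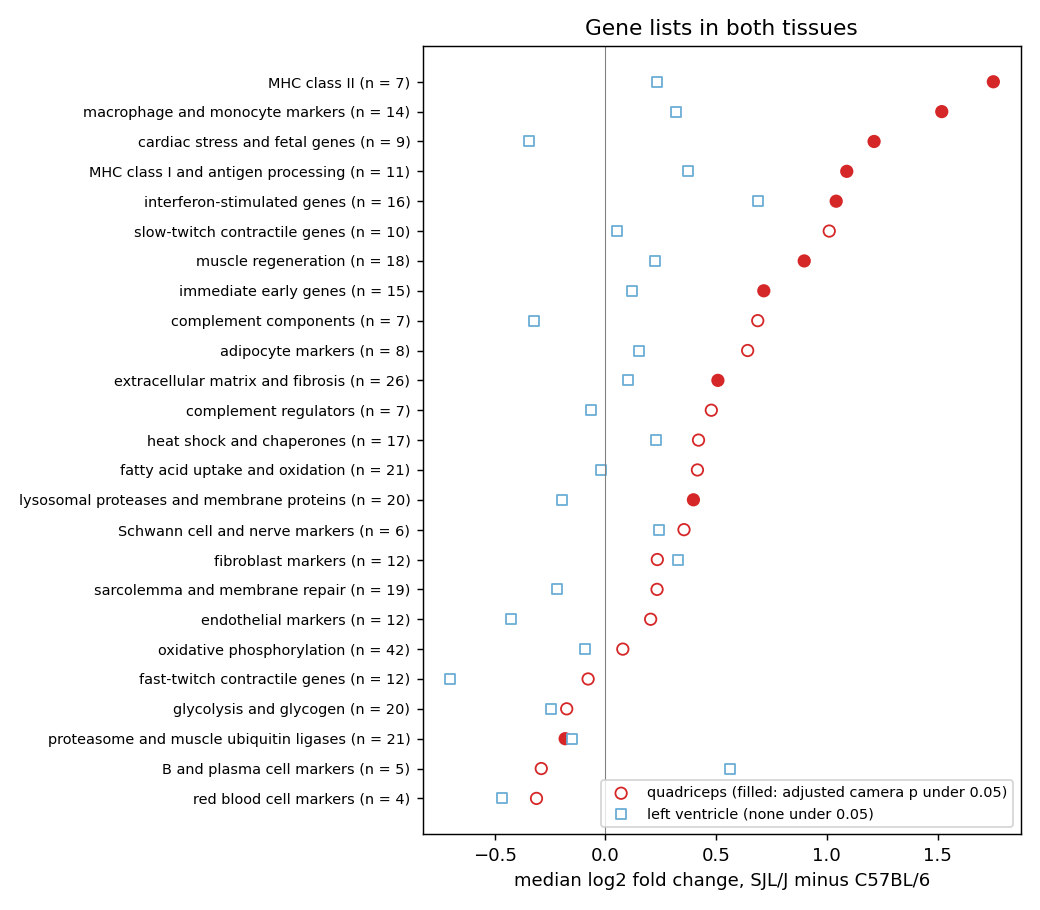
Median log2 difference between SJL/J and C57BL/6 over the tested genes of each list, circles for quadriceps (filled where the camera adjusted p with preset correlation was under 0.05) and squares for left ventricle. The 10 filled lists run from -0.18 for the proteasome to 1.75 for MHC class II, and in left ventricle 0 lists were called.

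The normal tissues themselves, left ventricle against quadriceps of C57BL/6 mice, differed in 2723 genes, 1651 higher and 1072 lower in left ventricle. No fluidics run held C57BL/6 arrays of both tissues, so tissue and run cannot be told apart in this contrast. With chip lot as a block, where C57BL/6 array 4 alone stands for quadriceps, 112 of the 2723 genes changed sign. Myzap, a protein of cardiac cell junctions (7.82 ± 0.68, adjusted p = 1.93e-06), Ryr2 (7.45 ± 0.72, adjusted p = 4.33e-06), Perp (6.49 ± 0.69, adjusted p = 1.01e-05), Nppb, a natriuretic peptide (6.48 ± 0.56, adjusted p = 1.92e-06), and Tnnt2 (6.36 ± 0.60, adjusted p = 3.59e-06) had the largest called increases. Their quadriceps signal is weak on most arrays and higher on C57BL/6 array 2, which carried heart transcripts, so sizes and order are uncertain. Over the alternatives Myzap ran from 5.43 to 8.90, Ryr2 from 5.40 to 8.48, Perp from 4.70 to 7.43, Nppb from 5.38 to 7.31 and Tnnt2 from 5.45 to 7.21. The fast myosin Myh1 (-8.43 ± 1.28, adjusted p = 0.000161), the fast troponin Tnnt3 (-7.71 ± 0.92, adjusted p = 2.49e-05), Ryr1 (-7.22 ± 0.73, adjusted p = 6.51e-06), Actn3 (-7.20 ± 0.97, adjusted p = 6.58e-05) and Myh4 (-6.86 ± 1.40, adjusted p = 0.00143) had the largest called decreases. C57BL/6 left ventricle array 5 carried skeletal transcripts (Myh4 5568, Myh1 1099 and Actn3 939.9), and 2 of the other Myh1 values in C57BL/6 left ventricle lay under the floor of 3.1. The sizes and order are thus uncertain: over the alternatives Myh1 ran from -9.99 to -6.58, Actn3 from -8.63 to -6.49 and Myh4 from -8.34 to -5.89. Cd55 was lower in left ventricle than in quadriceps (-2.09 ± 0.41, adjusted p = 0.00104). Endothelial markers (11 higher and 0 lower of 12, median 1.76, camera adjusted p = 3.90e-06), fatty acid genes (18 higher and 2 lower of 21, median 1.14, camera adjusted p = 0.000152), macrophage markers (11 higher and 0 lower of 14, median 1.36, camera adjusted p = 0.00304), MHC class I (10 higher and 0 lower of 11, median 1.43, camera adjusted p = 0.000152), interferon-stimulated (12 higher and 0 lower of 16, median 1.23, camera adjusted p = 0.00608) and matrix genes (16 higher and 0 lower of 26, median 0.71, camera adjusted p = 0.00116) were higher in left ventricle. Fast-twitch (0 higher and 11 lower of 12, median -5.38, camera adjusted p = 3.90e-06), glycolysis (4 higher and 16 lower of 20, median -1.10, camera adjusted p = 0.000152) and proteasome genes (0 higher and 15 lower of 21, median -0.50, camera adjusted p = 2.06e-05) were lower. Thus 9 of 25 lists were called, and 0 with an estimated correlation (smallest adjusted p = 0.141). Groups did not overlap for 1963 of the called genes, against 42.8 by chance among all. Median centring moved the median by -0.203, and 1139 of its 2614 called genes were higher; quantile normalization gave 1413 of 2656. In genes called between left ventricle and quadriceps of C57BL/6 mice the count was 1647 with run as a random block.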

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

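The tests that weigh explanations for the 3 patterns of the next 3 paragraphs were chosen after the results were seen, while the comparisons with other splits of the arrays were set before. Other splits were tried for each count, drawing 100 splits of the same sizes. The real split alone (1 of 100) gave as many genes for all 5 counts. For each count but that of both tissues, this argues against a random split of the arrays. It does not tell strain or tissue from fluidics run, nor strain from RNA integrity, since these overlap. In quadriceps the real count was 634 and the highest other 20, in left ventricle 1822 and 442. In the interaction it was 875 and 470, between the C57BL/6 tissues 2723 and 0, and for genes called the same way in both tissues 171 and 0. Other splits of quadriceps called at most 20 genes, so none could reach 171, and this last comparison does not test the overlap.

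SJL/J quadriceps arrays 1 and 5 carried cardiac transcripts. Over 105 genes that the heart share does not use and that C57BL/6 heart holds 4- to 16-fold higher, their median share was 0.392 and 0.562, against -0.0187 to 0.0338 on C57BL/6 quadriceps arrays, which is consistent with heart RNA in these libraries. Exchanged tissue labels would leave the skeletal share under 0.2, and its lower value was 0.384. Muscle regeneration would raise regeneration genes that heart holds at lower levels, and their median difference from arrays 2 to 4 was -0.88 on the log2 scale over 10 genes (quartiles -1.63 and -0.51). The skeletal share argues against exchanged labels. The regeneration value argues against regeneration alone. Heart RNA would by itself lower these genes, since the skeletal shares of the 2 arrays were 0.4999 and 0.384. The value therefore cannot test regeneration alongside heart RNA, and how heart RNA would have entered stays open.

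On the strain index, SJL/J quadriceps array 5 lay between the strains. The index of 0.438 is the pattern itself, so it cannot support C57BL/6 heart RNA in this library, which stays open. SJL/J heart RNA is argued against, because over 39 genes with under 2-fold difference between the C57BL/6 tissues the index was 0.382, and the other SJL/J arrays lay between 0.873 and 1.18. Most of those arrays helped define the index, and array 5 did not. Pttg1 read 918 on this array against 142 to 184 on the other SJL/J quadriceps arrays. No biological explanation was tested.

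Genes lower in SJL/J left ventricle were also low on SJL/J quadriceps array 1: over 67 genes chosen as lower in SJL/J left ventricle and not in SJL/J quadriceps arrays 2 to 4, with a median left ventricle difference of -1.77, this array lay -1.01 from the other quadriceps arrays and array 5 lay -0.04, a gap that the choice itself favours. A strain difference confined to heart, with SJL/J heart RNA on array 1, would place these genes at the level its heart share predicts. They lay -0.55 from it (quartiles -1.08 and -0.01, 51 genes below), and as the quartiles span the bound of -0.5 this cannot be told apart from library or RNA quality shared with the SJL/J left ventricle arrays. A mixture cannot lie below both of its sources, and 10 of the 67 genes read lower on array 1 than on the 5 SJL/J left ventricle arrays and quadriceps arrays 2 to 4. Chance gives 7.44 of the 67 genes. Over all tested genes 7.46% read so, a smaller share than 10 of 67, and these values exclude neither explanation. For the latter, the Gapdh ratio of array 1 was 0.267, inside the 0.101 to 0.470 of those arrays, and this array alone had the second wash protocol; the quartile rule was added after the median of -0.554 was seen.

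Single arrays stood apart within their group of 5 in 40 of 412 tests of named genes and array measures, where chance flags about 1 in 20 groups, or 20.6. The measure is the gap from the array to its nearest neighbour over the range of the group (Dixon's ratio). On SJL/J left ventricle array 1 it was 0.725 for Cd59a, 0.737 for Gadd45a, 0.856 for Lum, 0.74 for Slc27a1, 0.758 for Psap, 0.775 for Sdc4 and 0.964 for the skeletal share. For SJL/J quadriceps array 1 it reached 0.725 for Psma2, 0.809 for Atp5k, 0.714 for Cox7a1, 0.892 for Cox8b, 0.744 for Atp5e and 0.77 for Psma1. SJL/J quadriceps array 5 gave 0.861 for Pttg1, 0.833 for Fabp3, 0.817 for Snhg6, 0.827 for Etfb, 0.775 for Egr1 and 0.832 for the strain index. It came to 0.867 for Cd68, 0.752 for Psmb9, 0.731 for Atp5e, 0.869 for Gatm and 0.779 for Ctss on SJL/J left ventricle array 5. On C57BL/6 quadriceps array 4 it was 0.784 for Psma2, 0.79 for Irf9 and 0.747 for Sdhb. For C57BL/6 left ventricle array 3 it reached 0.747 for Fgfbp1, 0.811 for Zfp30 and 0.741 for Postn. C57BL/6 quadriceps array 2 gave 0.782 for Ryr2 and 0.757 for Rrad. It came to 0.836 for Decr1 and 0.863 for the skeletal share on C57BL/6 left ventricle array 5. On C57BL/6 left ventricle array 1 it was 0.757 for Fkbp8. For SJL/J quadriceps array 4 it reached 0.72 for Myog. C57BL/6 left ventricle array 4 gave 0.809 for Cdkn1a. It came to 0.782 for Ccnd2 on SJL/J left ventricle array 4. On C57BL/6 quadriceps array 1 it was 0.829 for H2-D1. For SJL/J left ventricle array 2 it reached 0.714 for Cidea.

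A second set of values marks differences between the tissues: 76 named genes and 10 lists whose strain difference in quadriceps minus that in left ventricle passed the interaction test, genes by limma and lists by camera at the preset correlation, with adjusted p from 1.74e-08 to 0.0498. Among immune genes this difference was 1.67 for Tyrobp, 3.13 for H2-Ab1, 1.42 for Cd74, 1.09 for Psme1, 1.21 for Irf1, 1.24 for Cd68, 2.30 for Cd52, 2.46 for H2-Aa, 2.15 for Psmb9, 0.92 for H2-K1, 1.10 for H2-D1, 2.07 for Ctss and 1.12 for Mpeg1. Among complement genes this difference was 1.14 for Cd59a, -2.77 for Cd55, 1.78 for C1qc and 2.40 for C1qa. In matrix and lysosomal genes this difference was 1.30 for Postn, 0.99 for Col6a2, 2.95 for Serpinh1, 1.17 for Bgn, 1.30 for Grn, 1.34 for Ctsd, 1.10 for Ctsb, 1.89 for Ctsh and 1.01 for Psap. In annexins and other membrane repair genes this difference was 0.93 for Anxa2, 0.99 for Anxa4, 1.76 for Capns1, 1.01 for S100a10 and 1.23 for Anxa5. In regeneration, stress and immediate early genes this difference was 3.80 for Mt2, 1.13 for Btg2, 5.00 for Ankrd1, 1.33 for Gadd45a, 2.42 for Csrp3, 1.07 for Nes, 1.09 for Zfp36, 3.70 for Mt1, 2.35 for Ier3, 1.67 for Cdkn1a, 1.19 for Egr1, 0.84 for Igf2 and 1.54 for Ier2. In mitochondrial and fatty acid genes this difference was 2.67 for Atp5k, 2.15 for Cox7a1, 1.43 for Decr1, 3.22 for Cox8b, 0.87 for Sdhd, 2.52 for Slc27a1, 2.80 for Atp5e, 2.58 for Fabp3, 1.11 for Etfb and 3.12 for Uqcr11. In proteasome subunits this difference was -0.76 for Psma3, -0.87 for Psmc2 and -0.61 for Psma1. Of the other named genes it was 4.53 for Rrad, 4.40 for Ucp1, 4.01 for Cidea, 3.74 for Ccnd2, 3.55 for Fkbp8, 2.89 for Mmp12, 2.38 for S100a4, 2.002 for Sdc4 and 1.42 for a probe set that carries the symbol of a microRNA and whose target was not checked. It was negative at -1.22 for Pla2g12a, -1.496 for Zfp30, -1.63 for Kpna2, -1.77 for Prps1l3, -2.54 for Inmt, -2.60 for Socs1, -2.81 for Fgfbp1, -2.81 for Mstn, -2.88 for Pla2g7 and -2.98 for Mup5. The call of Gadd45a ended without SJL/J quadriceps array 2 (1.18, adjusted p = 0.0511). With an estimated correlation 0 of the lists passed (smallest adjusted p = 0.152). For lists the median was 1.18 for macrophage and monocyte markers, 0.82 for MHC class I and antigen processing, 1.196 for MHC class II, 0.46 for extracellular matrix and fibrosis, 0.80 for muscle regeneration, 0.50 for sarcolemma and membrane repair, 1.02 for cardiac stress and fetal genes, 0.46 for fatty acid uptake and oxidation, 0.55 for lysosomal proteases and membrane proteins and 0.37 for immediate early genes.

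Probe sets without a single gene symbol take no part in the gene counts. Of 669 that passed the filter, limma called 88 between the strains in quadriceps (49 higher and 39 lower) and 226 in left ventricle (116 higher and 110 lower).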

How the results depend on the processing

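Counts shifted with the choices made. In quadriceps, 634 genes were called in the deposited scaling. All 20 arrays in one fit gave 1245, array weights 1402, a 2-fold limit 272 and an exact rank-sum test 0. In that test the smallest exact p with 5 against 5 arrays, 0.00794, adjusts to 0.067 when 639 genes are fully separated, so the 0 reflects its limit. Leaving out single arrays gave 411 to 959, the lowest without C57BL/6 array 2 or SJL/J array 2 and the highest without C57BL/6 array 4; C57BL/6 array 3 gave 413 and SJL/J array 3 gave 419. Without run 3 and C57BL/6 array 4 the count was 1178, with the Gapdh covariate 279, and among genes under 2-fold between the tissues 262. In left ventricle the 1822 became 1027 with all arrays in one fit, 344 with a 2-fold limit, 1190 with the rank-sum test and 256 with the Gapdh covariate. Fluidics run as a block left 48, and leaving out single arrays 1456 to 2093. The 875 interaction genes became 1817 with array weights, 485 with a 2-fold limit, 284 with run as a block, 208 with run as a random block, 1782 without run 3 and C57BL/6 quadriceps array 4, and 367 among genes under 2-fold between the tissues. Leaving out single arrays gave 672 to 1339, the highest without C57BL/6 quadriceps array 4. The 2723 tissue genes became 1330, 1647 and 1265 with a 2-fold limit, run as a random block and genes under 2-fold, and 2434 to 3132 with an array left out. Genes called the same way in both tissues, 171, became 337 with array weights, 39 with a 2-fold limit, 0 with the rank-sum test, 6 with run as a block, 267 with chip lot as a block (where C57BL/6 array 4 stands alone), 24 with the Gapdh covariate, 99 among genes under 2-fold, and 114 to 223 with an array left out. In left ventricle camera called 0 lists, and 1 with the Gapdh covariate. Signs reversed in quadriceps for Sdhb with run (-0.27) and with chip lot (-0.29) as a block, and in left ventricle for Cd55 with run as a block (-0.21). The Gapdh covariate reversed Ctss (-0.0204), B2m (-0.0515) and Cd74 (-0.17) in left ventricle, and run as a block reversed Psme1 in the interaction (-0.0421). In each case the cause was not tested. Run as a block rests on 1 run per tissue, and 48 of 65 followed quadriceps entries, 17 of 67 in left ventricle and 22 of 55 in the interaction kept their direction and side of the threshold. With the Gapdh covariate 51, 27 and 52 did. The alternatives on run 3, tissue shares, RNA quality, the random block and the genes under 2-fold were added after the data were seen. For 13 complement genes, 39 entries were dropped from the followed names after their values under the alternatives were seen. Of these entries 11 had passed the test, all in the contrast of normal tissues, and the others had not. Among their 1182 values under alternatives 65 changed sign, 30 newly passed the threshold, and 0 passed it with a reversed sign. Signals near background limit the fold changes of weak genes, since probe set signal compresses there and carries no count of molecules.

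Array numbers were tried as a replicate block. Within quadriceps and within left ventricle the block joined same-numbered arrays of the strains, which are different mice. In the interaction and between the tissues it joined same-numbered arrays of the tissues of the same strain. With these blocks 504 genes were called in quadriceps, 1508 in left ventricle, 604 in the interaction, 2530 between the tissues and 128 in both tissues. In the pairing check, same-numbered arrays of the tissues correlated at -0.067 to 0.062 in C57BL/6 and -0.214 to 0.012 in SJL/J after group means were removed. Across strains they correlated at -0.261 to 0.132 in quadriceps (2 of 5 pairs over 0.1) and at -0.188 to 0.113 in left ventricle (1 of 5).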

Other observations

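Cell type and metabolic groups in left ventricle held called genes although their lists were not called. Of 12 endothelial markers 6 fell in SJL/J, led by the water channel Aqp1 (-2.49 ± 0.20, adjusted p = 2.21e-06). The others included Tie1 (-0.63 ± 0.13) and Flt1 (-0.58 ± 0.16), while Eng rose (0.75 ± 0.22). Within run 3 the medians of the endothelial, glycolysis and fatty acid lists were -0.07, 0.08 and 0.15, against -0.43, -0.25 and -0.02 over all arrays. RNA integrity was lower in SJL/J left ventricle (Gapdh ratio 0.300 against 0.797), 1822 of 5392 genes were called there, and the genes named here that lie outside the naming rule were not followed under the alternatives. Of 20 glycolysis genes 8 fell, among them Pfkm, muscle phosphofructokinase (-1.76 ± 0.27), Pkm (-1.10 ± 0.24) and Tpi1 (-0.90 ± 0.19). Fatty acid genes fell in 6 cases, among them Fabp3, the heart fatty acid binding protein (-1.88 ± 0.21), Slc27a1 (-2.54 ± 0.44) and Decr1 (-0.83 ± 0.09). Of 17 chaperone genes, 4 rose, 4 fell and 9 did not pass the test. Chaperone genes had 4 higher and 4 lower when adjusted over the list alone, a median of 0.23 and camera adjusted p = 0.875. Their mean was -0.05, opposite in sign. Serpinh1, Hspb8 (-1.12 ± 0.21), Hspa4 (-0.63 ± 0.08) and Cryab (-0.46 ± 0.10) were the falls. Among 12 fibroblast markers, 5 rose, 2 fell and 5 did not pass the test. Fibroblast markers had 5 higher and 2 lower when adjusted over the list alone, a median of 0.33 and camera adjusted p = 0.684.

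The remaining lists in left ventricle gave these values. Immediate early genes had 3 rises and 2 falls of 15 (median 0.12, camera adjusted p = 0.862), slow-twitch genes 2 and 2 of 10 (median 0.05, camera adjusted p = 0.862, with a mean of -0.16), and fast-twitch genes 1 and 0 of 12 (median -0.70, camera adjusted p = 0.601). B and plasma cell markers had 2 rises of 5 (median 0.56, camera adjusted p = 0.297), adipocyte markers 1 fall of 8 (median 0.15, camera adjusted p = 0.873, test direction down), red blood cell markers 1 fall of 4 (median -0.47, camera adjusted p = 0.465), and nerve markers 0 calls of 6 by limma (median 0.24, camera adjusted p = 0.504), 0 also over the list alone. Of the lists too small for the set test, mast cell markers had 1 rise of 2, and limma called 0 of 2 T and NK cell, 3 neutrophil and 3 atrial markers, 0 also over the list alone.

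Myh6, the cardiac myosin heavy chain, read 13893 and 14702 on SJL/J quadriceps arrays 1 and 5, 4623 on array 3 and 82.3 and 225.2 on arrays 2 and 4. In C57BL/6 quadriceps it read 3392 on array 2 and 93.5 to 870 on the others. Myh4, a fast skeletal myosin, read 8512 on SJL/J left ventricle array 1 and 5568 on C57BL/6 left ventricle array 5, against 2.20 to 777 on the other 8 left ventricle arrays.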
